A study of Mus musculus with 2 samples.

How the data were processed

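H3K4me3 chromatin immunoprecipitation was done on bone marrow cells enriched for CD117 and then for Sca1 on magnetic beads, with the antibody Abcam ab8580, per the labels. Samples were grouped by genotype from the labels, giving 1 WT and 1 Mll-PTD library. Bowtie 0.12.7, HOMER 4.7 and the mm9 build are named, per the submitters' processing notes.

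The authors deposited 1 list of regions. Per the file headers, it was made by the HOMER peak finder in histone style on the Mll-PTD tags, with the WT tags in the place of an input. Peaks of 500 bases were joined into regions of variable length, with a fragment length of 250 bases, a genome size of 2000000000 bases, at most 2 tags considered per base and a false discovery rate of 0.001, which set a threshold of 30 tags. A region had to exceed WT 4-fold with a Poisson p-value of at most 0.0001, per the file headers; 776 putative peaks were removed by the WT filter and 37 for clonality. The headers also give 349243 putative peaks, from which these removals do not lead to 41561 regions, and they do not say at which stage the removals were counted. WT served as the control, so the list can hold only regions higher in Mll-PTD, and no non-immunoprecipitated input was used here.

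The deposited signal columns hold Mll-PTD tags per 10000000 tags, Mll-PTD tags scaled to the WT library size and unscaled WT tags, with 0.5 where WT had no tag. The fold and the p-value per region are the authors' deposited values. The ratio of the authors was used only to filter by fold, and the highest p-value in the authors' deposited table was 3.45e-07. The score of the tallest peak and the clonal fold are the authors' deposited scores. These values describe regions within this list, and their p-value is not a test between genotypes.

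The quotient of the scaled columns gave a WT library of 43579199 tags. Dividing the scaled Mll-PTD tags by 0.750 returned whole tags within 0.1 for 100% of regions, and these tags were used for intervals. The ratio of a region is scaled Mll-PTD tags over WT tags, with an exact (Clopper-Pearson) 95% interval. Medians are of log2((Mll-PTD tags + 1)/(WT tags + 1)) where stated. Where WT had 0 tags, a bound against 3 tags is given. Tags of 1 library are not independent molecules, so intervals and bounds cover counting error only. Shares carry exact Clopper-Pearson binomial intervals. Regions were also counted per chromosome, per 1-Mb bin and per length class.

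Named regions follow a rule written before the data were examined: among regions whose larger tag count was at or above the median, the 15 with the highest ratio and the 10 with the most tags. For this rule the ratio was ranked as the log2 ratio with a pseudocount of 1. The rule asked for regions near gene starts and for the Mll gene, which needs gene positions in mm9. Positions of that build were not used here, so regions are named by position, and the promoter share, the 21 gene lists, the Mll gene and its Hox targets were not analysed here. The length classes, the 1-Mb bins and the share of regions with no WT tag were chosen after seeing the data.

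The ratio, its interval and the count of regions with no WT tag were tested on simulated data. Tags were drawn for 41561 regions with a ratio of 7.5, and of 60 in 200 of them. The 4-fold threshold was not applied to these tags, so the check does not cover how the list was selected. With a pseudocount of 1 on both sides, the median log2 ratio came out at 2.72 against 2.63 simulated. Of 5000 intervals, 97.5% held the simulated ratio, and 1036 regions had no WT tag against 1071 expected. Alternatives were another pseudocount (5 or 0.5), a fold of 8, a p-value of 1e-05, regions with more tags, merged regions and left-out chromosomes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.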

Results

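Trimethylation of lysine 4 on histone H3 (H3K4me3), a mark of active and poised promoters, was profiled by chromatin immunoprecipitation and sequencing in bone marrow LSK cells of C57BL/6 mice. LSK cells are the lineage-negative, Sca1-positive, KIT-positive fraction that holds blood stem and progenitor cells. The cells used here were enriched for CD117 (KIT) and then Sca1 on magnetic beads, so other cell types may be present. One library came from wild-type (WT) mice and 1 from heterozygous mice with a knock-in of the partial tandem duplication of Mll (Mll-PTD). Mll, now named Kmt2a, encodes a histone H3K4 methyltransferase. The Mll-PTD library held 58083118 tags, and the scaling of the deposited tags gave 43579199 for WT. There was 1 library per genotype and no replicate, so every value below describes these 2 libraries, and every interval is a 95% interval that covers counting error only.

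The comparison asked where H3K4me3 tags were more frequent in Mll-PTD than in WT cells. The deposited list held 41561 regions in which Mll-PTD tags exceeded WT tags at least 4-fold. They covered 34.4 Mb of the mm9 genome. The list was called in that direction alone, so it holds no region that was higher in WT, and such regions were not analysed here. The regions took 4.62% of all Mll-PTD tags (exact binomial interval 4.62% to 4.63%) and 0.600% of all WT tags (0.598% to 0.602%), and the ratio of the summed tags after scaling to library size was 7.70 (7.67 to 7.73).

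Most regions were short and held few tags. Of all regions, 23662 (56.9%) had the minimum length of 500 bases, 7470 (18.0%) were longer than 1000 bases and 1063 (2.56%) reached 3000 bases. The median region held 29.3 scaled Mll-PTD tags (quartiles 24 and 45) and 4 WT tags (quartiles 2 and 6). The median log2 ratio with a pseudocount of 1 was 2.68 (quartiles 2.23 and 3.46). In the 35963 regions with at least 1 WT tag the median ratio was 6.83 (quartiles 5.11 and 10.5), and over all regions, with those without a WT tag at their bound against 3 tags, it was 7.5. The count depends on the fold that is asked for, since 19553 regions reached 8-fold in the authors' deposited table, which sets 0 WT tags to 0.5, and 18014 reached it with those regions at a bound against 3 WT tags.

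Median ratios lay between 6.20 and 7.73 in every length class. Among regions with a WT tag, the median ratio was 6.20 in regions of 500 bases (quartiles 4.76 and 10.5), 7.58 in regions of 1001 to 1500 bases (5.76 and 11) and 7.73 in regions of at least 3000 bases (6.24 and 9.17). WT tags stood at a median of 6.00 per kb in regions of 500 bases and 6.73 per kb in regions of at least 3000 bases, and scaled Mll-PTD tags at 49.6 and 52.4 per kb. Spread evenly over the genome size given to the caller, the tags of either library, at the WT library size, would stand at 21.8 per kb. Without the mitochondrial genome, the listed regions held 0.342 of that level in WT and 2.63 times that level in Mll-PTD. The 4-fold threshold alone keeps WT below the even level wherever Mll-PTD stands under 4 times that level, so the low WT level is partly set by how the list was made. The Mll-PTD level is partly set as well, since a peak needed 30 tags where the caller expected 11.4. In 34204 of the 41561 regions the tallest peak scored only 30 to 39. Short regions were limited by the 4-fold threshold, with 1842 of 10059 regions of 500 bases and 24 to 28 scaled Mll-PTD tags holding 6 WT tags, the most that limit allows, 1668 holding 5 and 943 holding 1. The number rose again to 1713 at 0 WT tags.

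**Figure D1:**
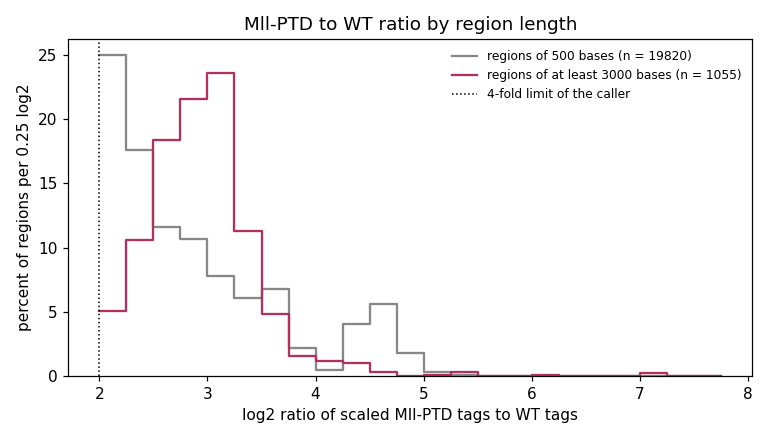
The horizontal axis gives the log2 ratio of scaled Mll-PTD tags to WT tags and the vertical axis the percent of regions in each step, for regions of 500 bases and of at least 3000 bases that hold a WT tag. The short regions pile up at the 4-fold limit, while the long regions centre on a median ratio of 7.73.

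Across 10 equal bins of regions ordered by mean tags of both libraries, the median log2 ratio was 3.60 in the lowest bin, 2.22 in bin 5 and 2.76 in the highest. The difference between the highest and the lowest bin was -0.84, and it changed sign to 0.29 with a pseudocount of 5. In the lowest bin 47.5% of regions had no WT tag, against 3.10% in the highest. The ordering includes the WT tags and the list has a minimum of Mll-PTD tags, so the lowest bin takes regions with few WT tags by construction, which raises its ratio. The tallest peak in a region is a score of the authors' caller. Among regions with a WT tag, the median ratio was 6.95 in those scoring 30 to 39 and 5.25 in the 40 scoring 200 or more. No WT tag was found in 14.2% of all regions scoring 30 to 39 and in 0% of those scoring 200 or more.

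The regions lay on all 19 autosomes, X, Y, the mitochondrial genome (M) and 12 sequences that hold unplaced or unlocalised contigs. Chromosome 7 held the most, with 3039 regions (7.31%, exact binomial interval 7.06% to 7.57%), followed by chromosome 4 with 2882 and chromosome 14 with 2675. Per Mb of the span between first and last region, chromosome 14 led the autosomes and X with 21.9 regions, followed by chromosome 17 with 20.9 and chromosome 7 with 20.3, and chromosome 18 was lowest among autosomes with 11.6. Among regions with a WT tag, the median ratio of autosomes ran from 6.49 on chromosome 3 to 7.27 on chromosomes 7 and 14. On X, 1906 regions (4.59%, 4.39% to 4.79%) had a median ratio of 6.29 over the 1815 with a WT tag, against 6.77 over all autosomes, and 6.5 against 7.5 with the others at their bound. On Y, 71 of 74 regions had a WT tag, with a median ratio of 9.75 and 467 WT tags in all. On the unlocalised Y sequence 850 of 1024 regions had one, with a median ratio of 9.04, or 8.39 with the others at their bound.

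**Figure D2:**
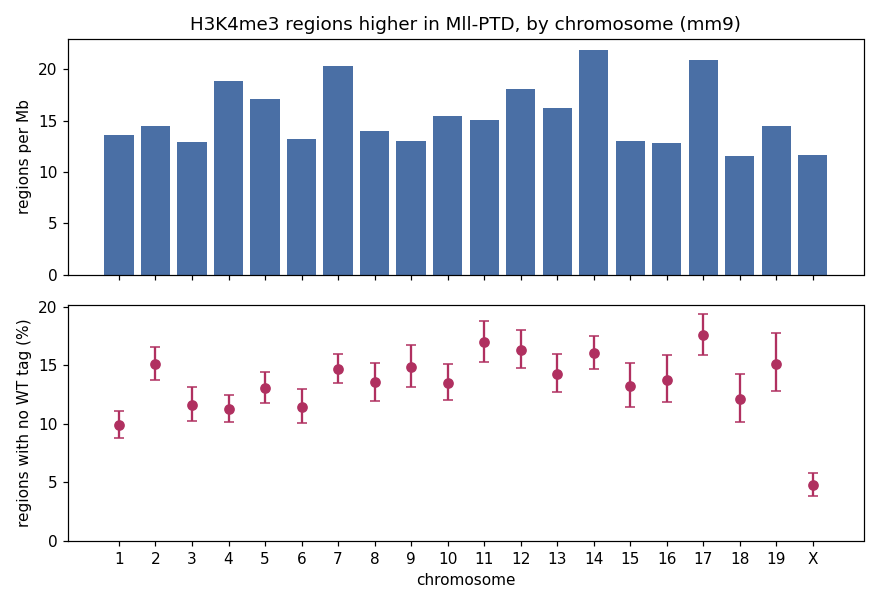
The upper panel gives regions per Mb of span for the 19 autosomes and X, and the lower panel the percent of regions with no WT tag, with exact 95% binomial intervals for counting error. Chromosome 14 has 21.9 regions per Mb, and X has the lowest share with no WT tag, at 4.77%.

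Regions were crowded in a few stretches. Of 1-Mb bins, 19 held at least 100 regions, and these bins took 2912 regions (7.31% of those on the autosomes, X and Y), while the other bins that held a region had a median of 12. The stretch of chromosome 14 from 42024278 to 44976544 held 546 regions, and the 447 with a WT tag had a median ratio of 8 (quartiles 5.64 and 12.2). Chromosome 7 from 21003651 to 23997846 held 486 (median ratio 8.63 in the 438 with a WT tag), chromosome 4 from 145046046 to 146999948 held 424 (6.76 in 396), chromosome 5 from 94001908 to 95996996 held 323 (8.14 in 263) and chromosome 12 from 23019596 to 24998362 held 240 (8.09 in 186). In the crowded bins together the median ratio of regions with a WT tag was 7.77, against 6.75 in the other bins. With regions without a WT tag at their bound, it was 8 against 7.33. The median region was also longer in the crowded bins, at 635 bases against 500. Over the whole list the median ratio differed with length, at 6.20 in regions of 500 bases and 7.58 in those of 1001 to 1500 bases. Crowded and other bins were not matched for length, so whether length accounts for the gap was not tested.

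**Figure D3:**
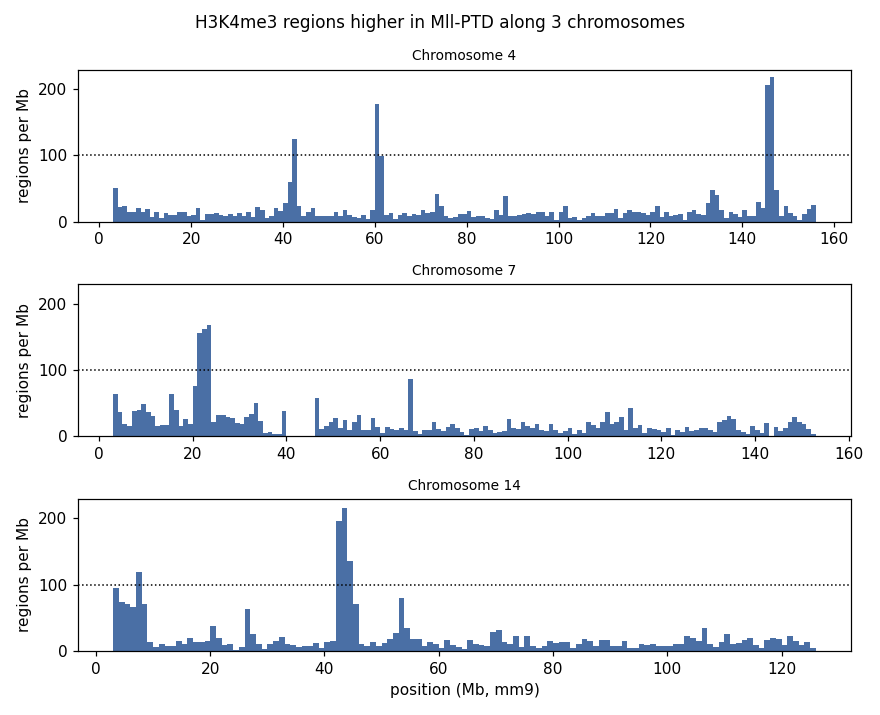
Regions per 1-Mb bin (vertical axis) are drawn along chromosomes 4, 7 and 14 (horizontal axis, Mb in mm9), with a dotted line at 100 regions. The stretches of chromosome 14 from 42 to 45 Mb, chromosome 7 from 21 to 24 Mb and chromosome 4 from 145 to 147 Mb rise above the line.

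Ranked by the log2 ratio with a pseudocount of 1, the 15 highest regions all had no WT tag. Each ratio given is a lower bound set against a floor of 3 WT tags per library. Without a pseudocount, 2 regions of at least 3000 bases with a WT tag had log2 ratios of at least 7. That is higher than every bound below except that of the chromosome 9 region. The first of the 15 lay on chromosome 9 from 117996935 to 118002195, where 643 Mll-PTD tags (482.4 after scaling) stood against 0 in WT, at least 161-fold higher. A region on chromosome 1 from 182171826 to 182175050 was at least 123-fold higher, with 369.9 scaled tags. A region on chromosome 5 from 111391037 to 111394149 was at least 122-fold higher, with 364.6 scaled tags. Next among the 15 came chromosome 12 from 117487127 to 117490816 (at least 95.5-fold higher) and chromosome 17 from 24392521 to 24394552 (at least 92.8-fold higher). The 15 regions lay on 12 chromosomes, were 1150 to 5260 bases long, and the lowest bound among them was 69.5-fold. These bounds take the Mll-PTD tags as exact and set 0 WT tags at 3, with all the error at that end. The exact 95% intervals share the error between both ends and so allow more WT tags. Their lower limits were therefore lower, 130.4 for the chromosome 9 region and 56.2 for the last of the 15.

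The 10 regions with the most tags in both libraries together had ratios from 4.78 to 11.6 and took 5.30% of the Mll-PTD tags in the list. First was the mitochondrial genome, from 129 to 16292, with 55603 Mll-PTD tags against 5440 WT tags and a ratio of 7.67 (7.46 to 7.89). Chromosome 10 from 7229269 to 7235583 had 21217 against 3329 tags and a ratio of 4.78 (4.61 to 4.96). Chromosome 7 from 67002138 to 67047723, the longest region at 45585 bases, had 16315 against 2059 tags and a ratio of 5.95 (5.68 to 6.23). Chromosome 1 from 24618301 to 24623313 had a ratio of 9.01 (8.53 to 9.52), and chromosome 7 from 71610406 to 71641295 had the highest of the 10, 11.6 (10.3 to 13.0). The chromosome 10 and chromosome 1 regions above were not typical of the list. They held 2521 and 2489 scaled Mll-PTD tags per kb, near the 2581 of the mitochondrial genome and far above the autosomal median of 49.6. Their WT tags were dense too, at 527 and 276 per kb, and no reason for these densities was tested. Mll-PTD tags exceeded 2 per base, the maximum the caller considers at a position, in 6 regions, the mitochondrial, chromosome 10 and chromosome 1 regions above included. The highest stood at 4.60 per base, so the deposited counts were not held to that maximum. How the maximum entered the calling of these regions is not known.

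No WT tag was found in 5598 regions (13.5%, exact binomial interval 13.1% to 13.8%). The share was 17.6% on chromosome 17, 17.0% on chromosome 11, 9.85% on chromosome 1 and 4.77% on X (3.86% to 5.83%). It fell with length, from 16.2% in regions of 500 bases to 5.41% in regions of 1001 to 1500 bases and 0.753% in regions of at least 3000 bases. In regions of at least 1000 bases it was 261 of 7473, where Poisson counts at the median WT level of the longest regions, 6.73 tags per kb, would give 1.27.

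**Figure D4:**
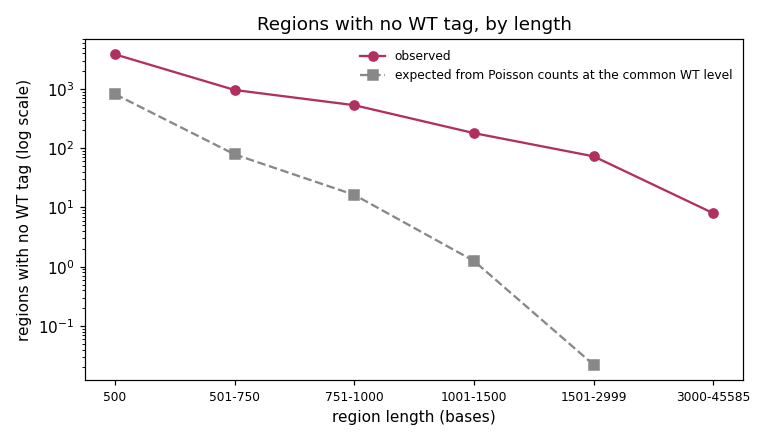
Regions with no WT tag are counted by length (horizontal axis, bases) on a log scale, beside the number expected from Poisson counts at 6.73 WT tags per kb; expected numbers under 0.01 are not drawn. Observed numbers stand above the expected ones in every class, with 3842 against 817 at 500 bases and 180 against 1.25 at 1001 to 1500 bases.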

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

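The tests of the shared ratio, of chance zeros and of piled tags were chosen only after the result was seen; the limits for neighbouring regions were set before that share was computed.

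Mitochondrial DNA carries no histones, and its tags lie outside the histone measurement. The Mll-PTD library still had 41718.4 scaled tags there, above the 5440 tags of WT. Contigs without a fixed place in the assembly held 103306 scaled Mll-PTD tags in 1727 regions, against 13647 tags in WT, a ratio of 7.57 (7.44 to 7.70).

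Long regions shared a narrow range of ratios: of those reaching 3000 bases and holding a WT tag, 796 (75.5%) lay between 5 and 10. A candidate explanation is that the libraries differ in how many tags are background, since the mitochondrial ratio was higher than that of 48% of these regions. That test decides nothing, because a ratio under 4 would have kept the mitochondrial genome off the list. Mll-PTD tags there reached 3.44 per base, above the maximum of 2 per position, to which the deposited counts were not held. A gain of H3K4me3 that differs from region to region predicts a wide spread, and the spread of log2 ratios was 1.53 times that of counting error. That test decides nothing either, because the list keeps only ratios of at least 4 and regions with no WT tag were left out of it. Background and H3K4me3 gain cannot be told apart with 1 library per genotype and no input, and the difference between genotypes stays open.

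The 261 regions of at least 1000 bases with no WT tag are more than chance zeros at the common WT level give, 1.27. Piled tags as the cause for most of them are argued against by the clonal fold, which was above 1 in 8.05% of them (5.05% to 12.04%). That is more than the 1.01% of regions with a WT tag, and the median clonal fold was 0.81 against 0.68. The caller had already removed putative peaks with a clonal fold above 2, so strongly piled regions could not be seen here. Missing stretches of 10 kb or more are argued against as the cause for the set, since 24.3% of 152 listed neighbours within 10 kb also had no WT tag (17.8% to 31.96%), although that is more than the 9.56% beside regions with a WT tag. Shorter missing stretches, base composition, reads dropped at repeats and a gain of H3K4me3 in Mll-PTD cells were not tested and stay open.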

How the results depend on the processing

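Chosen after seeing the data were the alternatives that set apart regions of at least 3000 or 1000 bases, crowded bins or regions with a WT tag, the 8-fold count at the bound, those without X, Y, M and contigs for the median ratio and tag trend, and all those for the share with no WT tag. Of 41561 regions, 19553 had a fold of at least 8 by the authors' deposited table (18014 with those without a WT tag at their bound) and 20928 a tag count at or above the median; merging and leaving out chromosomes or crowded bins kept the count within 1.5 times, and a p-value of 1e-05 could remove none, the highest being 3.45e-07. The median log2 ratio of 2.68 became 2.05 with a pseudocount of 5, 2.80 with 0.5, 2.75 at or above the median tag count, 2.91 in regions of at least 3000 bases, 2.65 without crowded bins and contigs and 2.55 in regions with a WT tag; its sign was fixed by the 4-fold threshold. The tag trend of -0.84 turned to 0.29 with a pseudocount of 5, which lowers ratios of small counts by construction, and was -0.23 in regions with a WT tag. The share on X moved from 4.59% to 3.93% at or above the median tag count. The share with no WT tag, 13.5%, was 9.82% at or above the median tag count, 3.49% in regions of at least 1000 bases and 13.8% without X, Y, M and contigs. The 10 named regions with the most tags stayed within their counting intervals with either pseudocount. The log2 ratios of the 15 with no WT tag depend on it, such as 8.92 on chromosome 9, which became 6.61 with 5 and 9.92 with 0.5. No paired analysis was possible because each genotype has 1 library. Centring on housekeeping genes, limits to gene starts, promoter shares and gene lists were not run, since gene positions in mm9 were not used here. Depth limits single regions, whose median WT count was 4.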

Other observations

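Mll-PTD tag density in regions with no WT tag differed with length. In regions of 500 bases, which held 3842 of the 5598, the median was 48 scaled Mll-PTD tags per kb with no WT tag and 49.6 with one, and in longer regions of up to 750 bases it was 50.2 and 50.5. In regions of at least 1000 bases, those with no WT tag held a median of 63.3 scaled Mll-PTD tags per kb (quartiles 49.6 and 86.7), and those with a WT tag 49.9 (45.4 and 56.3). Of these 261 regions 1 lay on X, and 8 reached 3000 bases. In the stretch of chromosome 17 from 6005710 to 6984551, 26.1% of 157 regions had no WT tag, and in that of chromosome 4 from 145046046 to 146999948 the share was 6.60% of 424. These values were looked at after the data had been seen, and no explanation was tested for them.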
